A study of Mus musculus with 9 samples.

How the data were processed

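The series holds single-cell RNA-seq of mouse embryonic stem cells that carry the CARLIN barcode array and Cas9. Per the labels' protocols, the cells grew as a monolayer on poly-D-lysine and received 1 of 3 retinoid treatments. ATRA (all-trans retinoic acid, which the labels call a pan-RAR agonist) was used at 1 µM, BMS753 (labelled RARα-specific) at 1 µM, and BMS641 with BMS961 (labelled RARβ- and RARγ-specific) at 0.1 µM each. The doses therefore differ between treatments. Cells were taken at days 4, 8 and 16, with 1 library per treatment and day, which makes 9 libraries in 9 groups. Per the labels, 100000 cells were seeded per well for day 4. For day 8, 40000 were seeded under ATRA and 20000 under the other treatments. For day 16 these numbers were 20000 and 10000. The day 16 wells spent the last 8 days in Neurobasal with B27 lacking vitamin A. Cells were freed with papain and loaded on the 10x Chromium 3′ v3 chemistry with a target of 8000 cells, and libraries were sequenced on a NovaSeq instrument. Ethanol wells named in the protocols have no library here and were not analysed. The CUT&Tag and spatial data of the wider study are not part of this series.

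Each library was deposited as a matrix of raw counts, that is, unique molecular identifiers (UMIs) per gene and barcode. Per the submitters' processing notes, the authors made these counts with Cell Ranger 7.0.1 on the mm10 genome and used Seurat 5 afterwards. No cell annotation by the authors was used here. The matrices list 32285 genes with Ensembl identifiers and symbols. Of these, 32158 identifiers (99.6%) were found in the GENCODE annotation at hand, and 38 symbols stood on more than 1 identifier. The values were whole numbers in every library, and 103486 barcodes were deposited in all.

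Barcodes were kept with at least 500 genes and at most 15% mitochondrial UMIs. Doublets were called per library with Scrublet in scanpy 1.11.5, with an expected rate of 0.8% per 1000 barcodes. The automatic threshold did not work. It marked 1460 cells (8.98%) of the library labelled BMS753 day 16, against 0.599% or less in each other library, where 4.41% to 16.6% were expected. Those calls were removed all the same, and 93558 cells stayed. UMIs were summed over the cells of a library and scaled to the library's total as CPM. Reads can be split between near-identical copies, so the levels of Ftl1 and its copy Ftl1-ps1 are uncertain.

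Each treatment was compared with each other treatment at each day (9 comparisons), and each day with each other day within a treatment (9 comparisons). With 1 library per group there is no replicate error, so no test was run and no p-value is given. A gene was called apart between a pair of libraries when its CPM differed at least 2-fold, reached 10 CPM in the higher library, and the exact 95% interval of its ratio excluded 1. That interval conditions on the summed UMIs and is binomial (Clopper-Pearson), as are intervals of shares. All intervals cover counting error only and describe these libraries, not the treatments. A ratio to 0 counts is given as a lower bound against 3 counts in the library, and a class share of 0 with the upper bound of 3 counts. The procedure was tested on simulated data with counting error alone, for ATRA against BMS753 at day 16, with 9851 genes and 50 genes per fold size. It called apart 0 of 50 genes at 1.5-fold, 50 of 50 each at 3-fold, 5-fold and 0.333-fold, and 0 of 9651 unchanged genes. The intervals held the true ratio for 94.0%, 92.0%, 96.0%, 98.0% and 95.1% of these genes. Variation between replicates was not simulated.

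The named genes followed a rule of size. For each pair of treatments at a day, and for day 16 against day 4 within a treatment, they are the 5 genes per direction with the largest log2 ratio of CPM plus 1, among genes with at least 20 CPM in the higher library. Within a class of cells they are the 3 per direction. Mitochondrial, ribosomal protein, haemoglobin and clone-named genes were left out. A few genes that met the rules are not reported here. Members of the gene lists could be named by level or by fold. The 31 lists are retinoid response, retinoid receptors, pluripotency, neural progenitor and radial glia, proneural, pan-neuronal, glutamatergic, GABAergic, motor and cholinergic neuron, astroglia, oligodendrocyte lineage, ependymal and choroid plexus, neural crest, primitive and parietal endoderm, visceral endoderm, mesoderm, mesenchymal and fibroblast, muscle, endothelial, macrophage and microglia, surface epithelium, forebrain and midbrain, 3 lists of Hox genes by paralog group, dorsal neural tube, ventral neural tube, proliferation, immediate early and stress, cholesterol synthesis, and hypoxia and glycolysis. A member counts as measured with at least 5 CPM in the higher library. A list with at least 3 measured members is given by the median log2 ratio of its measured members. Members counted as higher or lower are those called apart. A list's percentile among 10000 random lists of the same size, matched on mean expression, is a description of the libraries compared.

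Cells were clustered together after scaling to 10000 UMIs and a log transform, with 2000 variable genes, 50 principal components, 15 nearest neighbours, a Jaccard-weighted graph and the Leiden method at resolution 1 (igraph 0.11.9), which gave 34 clusters. A cluster was called X-like from 19 sets of marker genes when its best set passed a threshold on the mean log2 fold over the other cells and at least 3 of its markers were detected in over 10% of its cells. It stayed unnamed when more markers of another set stood among its top 10 genes, or when its depth was under 1 in 3 of its library's with none of its markers there. The threshold on the mean fold was set after the clusters had been seen. Shares of cells with a UMI of a gene were taken after each cell was thinned to 2000 UMIs, and shallower cells were left out.

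Cells of 5 libraries fell into 2 kinds by their UMIs on Ftl1 (ENSMUSG00000050708) and Ftl1-ps1 (ENSMUSG00000062382), which was seen in the data and not planned. A cell with at least 5 such UMIs was called Ftl1 kind when at most 25% of them lay on Ftl1-ps1, and Ftl1-ps1 kind when at least 60% did. Other cells were between or unassigned. Comparisons were repeated within each kind. The filters, comparisons, fold and CPM limits, lists, markers, clustering settings and the rule for named genes were chosen before the data were examined. The kinds, the naming threshold and the alternatives marked as added were not.

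The alternatives fixed beforehand were all deposited barcodes, a stricter filter (at least 1000 genes and at most 10% mitochondrial UMIs), TMM factors, equal weight for each cell, floors of 5 and 50 CPM, a 4-fold limit, a pseudocount of 5 in the log2 ratios, no floor for list members, doublet calls kept in, Leiden resolutions of 0.5 and 2, clustering on thinned cells, and clustering without 409 genes that correlate with the cell cycle at 0.3 or more. Within classes they were TMM factors, a floor of 50 CPM and classes from resolution 2. For shares of cells with a UMI they were thinning to 1000 UMIs and no thinning. The added ones were removal of the expected share of doublets by score, cells with at least 2000 UMIs, each kind of cells alone, and the library labelled BMS641+BMS961 day 8 without clusters 4 and 26. edgeR 4.0.16 in R 4.3.3 gave only the TMM factors. The rest ran in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, anndata 0.12.19 and matplotlib 3.10.9. A class was compared between libraries at day 16 with at least 100 cells in each.

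Total UMIs per library in the deposited matrices were 141252582, 77939446 and 64414484 at day 4, 151152498, 113452235 and 141153892 at day 8, and 191119921, 168094829 and 133602817 at day 16, each time for ATRA, BMS753 and BMS641+BMS961 in that order. Counting error is small above 10 CPM at this depth, and the missing replicate sets the limit.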

Results

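Transcripts were counted in single mouse embryonic stem cells and their progeny after 4, 8 and 16 days of retinoid treatment. The series asks how agonists of single retinoic acid receptors (RARs) steer the choice between neuronal and astroglial fates. ATRA acts on every RAR, BMS753 is the RARα-specific agonist, and BMS641+BMS961 are the RARβ-specific and RARγ-specific agonists given together. With 1 library per treatment and day no difference has a replicate check, and each comparison is between libraries. At day 4, 17331, 5258 and 5911 cells were kept under ATRA, BMS753 and BMS641+BMS961, with medians of 5525, 11397 and 7768 UMIs per cell. At day 8 these were 5479, 9195 and 13118 cells with 20280, 10990 and 8493 UMIs. At day 16 they were 13590, 14798 and 8878 cells with 7998.5, 6938 and 11311 UMIs. The dose of BMS641+BMS961 differed from that of the others, and from day 8 on the seeding density of ATRA did, so not every pair is at matched dose or density.

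In 5 of the 9 libraries the cells fell into 2 kinds. Ftl1 encodes the ferritin light chain and lies on chromosome 7 (GRCm38, 45457944 to 45459884), and Ftl1-ps1 is annotated as its copy on chromosome 13 (74399694 to 74407346). Cells of the Ftl1-ps1 kind made up 56.0% (95% interval 55.2 to 56.9) of the assigned cells under ATRA at day 4. At day 8 they made up 34.7% (33.4 to 36.0) under ATRA, 57.8% (56.7 to 58.8) under BMS753 and 21.3% (20.6 to 22.0) under BMS641+BMS961. At day 16 they made up 80.2% (79.5 to 80.9) under ATRA. None was found among the 32744 assigned cells of the other 4 libraries. In all, 8093 cells (8.65%) had too few UMIs of these genes to be assigned. The kinds also differed in Hprt (ENSMUSG00000025630), a purine salvage enzyme gene on chromosome X (52988137 to 53021659). It ranged from 0.601 to 2.86 CPM in the Ftl1-ps1 kind and from 48.9 to 86.9 CPM in the Ftl1 kind. In the same order, Rpl29 (ENSMUSG00000048758) ranged from 121 to 341 and from 866 to 1402 CPM, and the kainate receptor gene Grik3 (ENSMUSG00000001985) from 49.9 to 178 and from 3.36 to 45.7 CPM. Because the kinds are spread unevenly over the libraries, values within a kind stand beside many of the pooled ones.

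**Figure D1:**
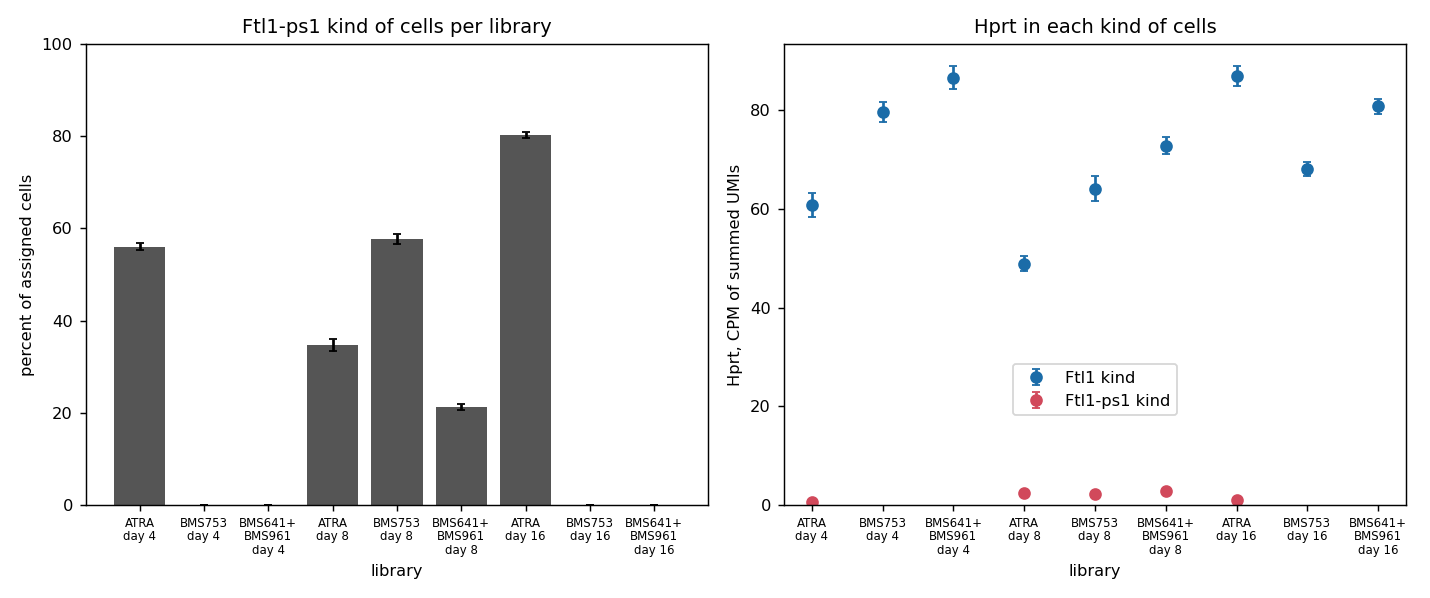
Left, percent of assigned cells of the Ftl1-ps1 kind in each library (bars), with Clopper-Pearson 95% intervals. Right, CPM of Hprt summed over the cells of each kind (points, exact Poisson 95% intervals), at most 2.86 CPM in the Ftl1-ps1 kind and at least 48.9 CPM in the Ftl1 kind.

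The classes of cells differed in size between treatments and days. At day 4, 26.2% of cells under BMS753 and 20.1% under BMS641+BMS961 were pluripotent-like, against 0.479% under ATRA, and 94.8%, 69.8% and 76.0% of cells under ATRA, BMS753 and BMS641+BMS961 stayed unnamed. Which of BMS753 and BMS641+BMS961 held more pluripotent-like cells is not settled. Cluster 21 (25.3% of cells under BMS641+BMS961 and 1.502% under BMS753), cluster 23 (7.63% under ATRA) and the small cluster 25 matched the pluripotent markers best but missed a threshold set after seeing the clusters. Clusters made from thinned cells gave 1.16%, 70.3% and 80.5% pluripotent-like cells under ATRA, BMS753 and BMS641+BMS961. At day 8, neuron-like cells made up 21.0% (19.9 to 22.1) under ATRA, 4.30% (3.89 to 4.73) under BMS753 and 0.648% (0.518 to 0.801) under BMS641+BMS961. Pluripotent-like cells were 4.76%, 50.4% and 25.9% in the same order, and neural progenitor-like cells 6.22%, 22.3% and 3.42%. The gap in pluripotent-like cells between BMS753 and BMS641+BMS961 rests largely on clusters 4 and 26 of the latter, since they were 51.2% and 18.3% of the Ftl1 kind but 59.2% and 56.6% of the Ftl1-ps1 kind. Neuron-like cells at day 8 were 25.6%, 5.16% and 0.328% of the Ftl1 kind and 6.41%, 1.71% and 0.486% of the Ftl1-ps1 kind, and neural progenitor-like cells 8.21%, 22.0% and 2.09%, and 3.03%, 19.2% and 6.62%. At day 16, neuron-like cells made up 4.29% (3.96 to 4.64), 23.1% (22.5 to 23.8) and 3.71% (3.32 to 4.12). Astroglia-like cells made up 2.72% (2.46 to 3.01), 11.2% (10.7 to 11.7) and 2.56% (2.24 to 2.91). Among cells of the Ftl1 kind the neuron-like shares at day 16 were 11.7%, 22.7% and 3.51%, and the astroglia-like shares 5.29%, 11.5% and 2.69%. No astroglia-like cell was found at day 4 and hardly any at day 8, with 0 of 5479 under ATRA, which allows up to 0.0548% (3 counts), 4 under BMS753 and 3 under BMS641+BMS961. With 1 library per group, a cluster mostly of 1 library may be that library and not a type of cell.

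**Figure D2:**
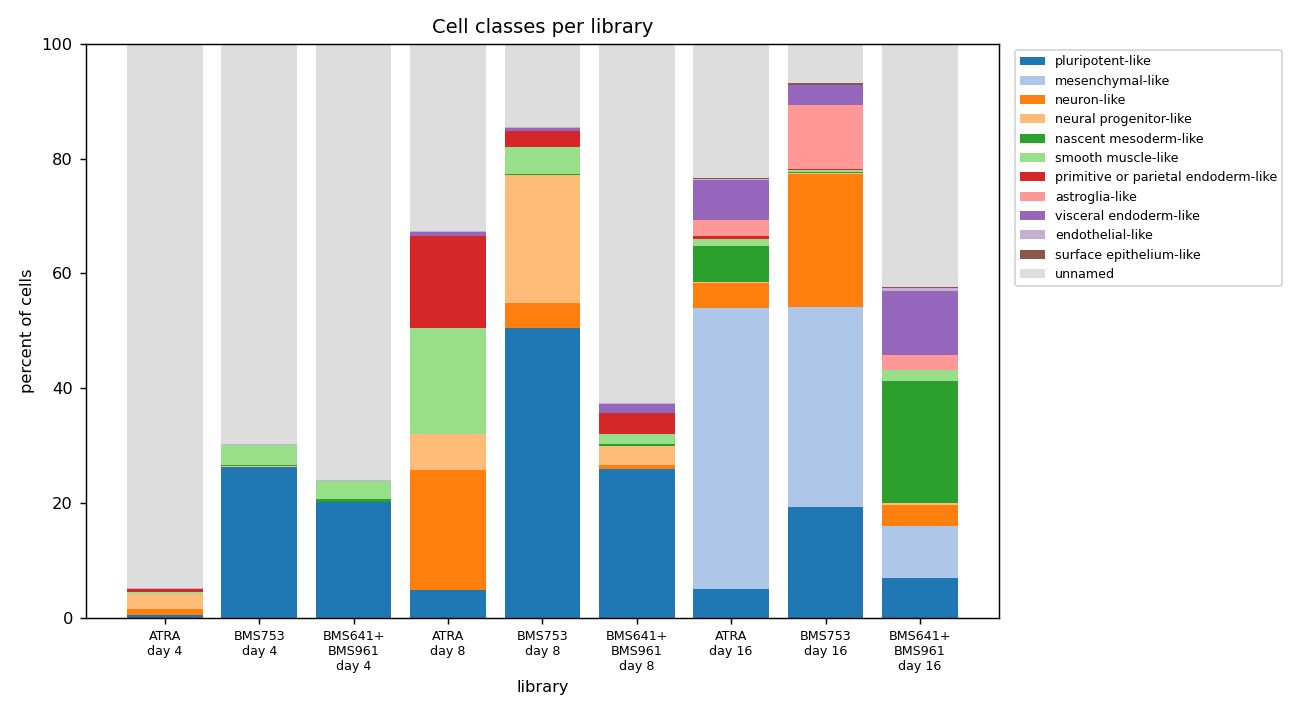
Percent of cells (vertical axis) in each class of cells, stacked per library (horizontal axis), with grey for cells of unnamed clusters. Neuron-like cells are 21.0% under ATRA at day 8 and 23.1% under BMS753 at day 16, and pluripotent-like cells are 50.4% under BMS753 at day 8.

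ATRA against BMS753 at day 4 asks what an agonist of every RAR does beyond one of RARα. Retinoid response, endoderm and Hox genes were higher under ATRA, and pluripotency genes lower. In the retinoid response list, 14 of 19 measured members were apart as higher and 1 as lower, with a median log2 ratio of 2.01, at percentile 100 of the random lists. Its members included Rarb (ENSMUSG00000017491), the receptor gene that RARs switch on, at 303 against 24.0 CPM, and Cyp26a1 (ENSMUSG00000024987), an enzyme that breaks down retinoic acid, at 241 against 1.71. Dhrs3 (ENSMUSG00000066026), which reduces retinal, stood at 167 against 17.8 CPM. Pluripotency genes had a median of −2.22 (percentile 0) with 14 of 18 lower and 1 higher. The core factors Pou5f1 (ENSMUSG00000024406, 49.8 against 222 CPM) and Zfp42 (ENSMUSG00000051176, 59.4 against 295 CPM) were among them. All 10 measured genes of primitive and parietal endoderm were higher (median 3.75), such as Gata6 (ENSMUSG00000005836), a determinant of that lineage, at 96.1 against 5.91 CPM, and the basement membrane collagen Col4a1 (ENSMUSG00000031502) at 916 against 41.6. Visceral endoderm genes had a median of 4.22 (5 of 6 higher), and muscle genes 1.87 (7 of 9 higher). Hox genes of groups 1 to 4 had a median of 1.74 (8 of 11 higher, 0 lower) and those of groups 5 to 9 a median of 1.07 (7 of 12 higher, 0 lower), for example Hoxa5 (ENSMUSG00000038253) at 126 against 14.6 CPM. The astroglia list had a median of 1.46 (4 of 8 higher, 1 lower) and the pan-neuronal list −0.88 (2 of 12 higher, 6 lower), a direction that flips to 0.25 when each cell weighs the same.

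By size, the genes with the highest ratio were Gkn2 (ENSMUSG00000030049), a gastrokine, at 148 against 0 CPM (at least 3847-fold higher), the chemokine gene Cxcl10 (ENSMUSG00000034855, 487-fold, 347 to 708), the pepsinogen gene Pga5 (ENSMUSG00000024738, 1315-fold, 638 to 3270), Stra8 (ENSMUSG00000029848), a retinoic acid target needed for meiosis (158-fold, 140 to 180), and Ftl1-ps1 (96.4-fold, 91.6 to 102). Lower under ATRA were the noncoding RNA Platr10 (ENSMUSG00000099370, 104-fold, 85.1 to 127), the hormone gene Trh (ENSMUSG00000005892, 44.1-fold, 41.4 to 47.1), the growth factor Fgf8 (ENSMUSG00000025219, 95.9-fold, 71.0 to 133) and Calca (ENSMUSG00000030669, 42.1-fold). The library labelled ATRA day 4 held 56.0% cells of the Ftl1-ps1 kind and the other none. Of its 6272 cells of the Ftl1 kind, 4730 lay in cluster 6, which was shallow (median 1767 UMIs) and held no Ftl1-ps1 kind cell, so values within that kind are largely those of cluster 6. Among cells of the Ftl1 kind the retinoid response list had a median of 1.67, pluripotency −3.56, primitive and parietal endoderm 4.12, Hox groups 1 to 4 1.65 and groups 5 to 9 1.28, whereas the pan-neuronal list turned to 0.15 (1 of 14 higher, 5 lower). Cxcl10 stood at 652 against 0.426 CPM there, and Stra8 at 12.8 against 3.28. In all, 1829 genes were apart as higher and 517 as lower under ATRA. TMM factors, which shift these log2 ratios by −0.32, made that 1073 and 1005, and within the Ftl1 kind it was 1777 and 1332.

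ATRA against BMS641+BMS961 at day 4 sets the agonist of every RAR beside the RARβ and RARγ agonists. Retinoid response, endoderm and Hox genes were again higher under ATRA and pluripotency genes lower. Retinoid response genes had a median of 2.29 (16 of 19 higher, 1 lower; percentile 100), with Rarb at 303 against 3.00 CPM. Pluripotency genes had a median of −2.22 (1 of 18 higher, 14 lower), primitive and parietal endoderm genes 4.08 (10 of 10 higher) and visceral endoderm genes 4.12 (5 of 6 higher). Hox genes of groups 1 to 4 had a median of 2.24 (8 of 11 higher) and those of groups 5 to 9 1.66 (8 of 11 higher), as for Hoxb4 (ENSMUSG00000038692) at 40.2 against 2.59 CPM. The astroglia list had a median of 1.90 (4 of 8 higher, 1 lower), with the lipid carrier Clu (ENSMUSG00000022037) at 603 against 25.8 CPM. No cell was astroglia-like at day 4, so these genes came from other clusters. The pan-neuronal list had a median of −1.08 (2 of 12 higher, 6 lower), and the dorsal neural tube list had members on both sides (−0.88, 1 of 4 higher, 1 lower). With equal weight per cell these medians flip to 0.13 and 0.25. The highest ratios were those of Gkn2 (at least 3186-fold), Cxcl10 (444-fold, 311 to 658), Cyp26b1 (ENSMUSG00000063415), another retinoic acid hydroxylase (578-fold, 370 to 960), Pga5 (586-fold, 343 to 1101) and Ftl1-ps1 (84.7-fold). Lower were Trh (68.8-fold), Fgf8 (249-fold, 185 to 345), Platr10 (86.8-fold), the mesoderm factor T (ENSMUSG00000062327, 1277-fold, 498 to 4691, from 4 UMIs under ATRA) and the Nodal coreceptor Tdgf1 (ENSMUSG00000032494, 28.8-fold). In all, 2276 genes were apart as higher and 478 as lower, or 1158 and 1125 with TMM factors (shift −0.43). Again 56.0% of ATRA's assigned cells and none of the other library's were of the Ftl1-ps1 kind. Within the Ftl1 kind it was 1956 and 1038, with medians of 2.19 for retinoid response, −3.44 for pluripotency, 4.37 for primitive and parietal endoderm, 0.11 for pan-neuronal and 0.47 for dorsal neural tube genes.

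BMS753 against BMS641+BMS961 at day 4 compares the RARα agonist with the RARβ and RARγ agonists. These libraries were close, with a correlation of 0.992 across 11256 genes, which are not independent replicates. In the retinoid response list 4 of 14 measured members were apart as higher under BMS753 and 0 as lower, with a median of 0.48 (percentile 100). Rarb stood at 24.0 against 3.00 CPM (8.00-fold, 6.89 to 9.32) and Crabp2 (ENSMUSG00000004885), which carries retinoic acid to its receptors, at 122 against 43.4 (2.80-fold, 2.69 to 2.92). The transcription factor genes Tshz1 (ENSMUSG00000046982, 3.38-fold) and Dach1 (ENSMUSG00000055639, 2.89-fold) and the sodium-calcium exchanger Slc8a1 (ENSMUSG00000054640, 3.11-fold) were higher too. Lower were T (6.17-fold, 5.58 to 6.83), Slc39a1 (ENSMUSG00000052310, 4.13-fold), Rpgrip1 (ENSMUSG00000057132, 3.57-fold), Amt (ENSMUSG00000032607, 3.02-fold) and Fgf8 (2.60-fold, 2.47 to 2.73). Hox groups 1 to 4 had a median of 0.37 (0 of 6 past 2-fold) and groups 5 to 9 a median of 0.36 (2 of 8 higher). Pluripotency genes lay at −0.06 and pan-neuronal genes at 0.02, with no member past 2-fold in either list. In all, 43 genes were apart as higher and 19 as lower, or 32 and 33 with TMM factors (shift −0.11). Neither library held cells of the Ftl1-ps1 kind.

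**Figure D3:**
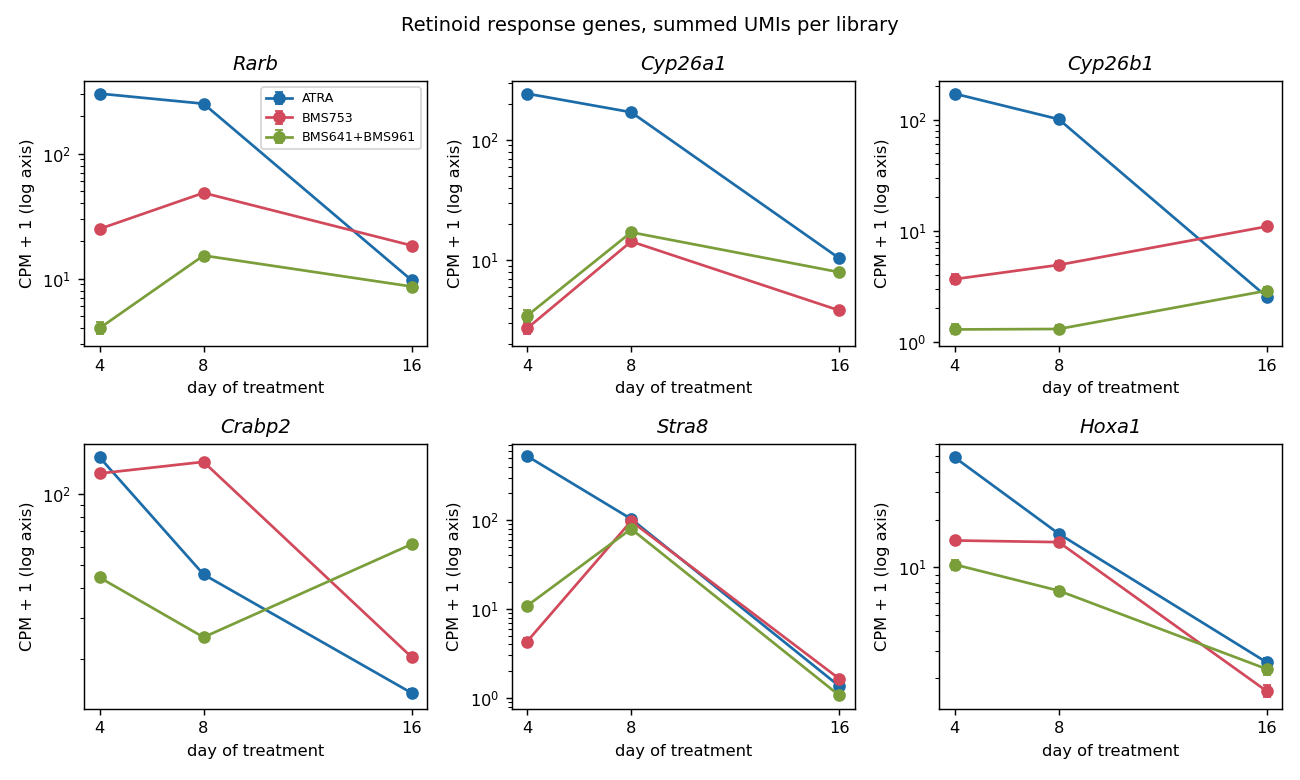
CPM plus 1 on a log axis against day of treatment for 6 genes of the retinoid response and Hox lists, with points for single libraries joined per treatment and exact Poisson 95% intervals. Rarb is 303 CPM under ATRA, 24.0 under BMS753 and 3.00 under BMS641+BMS961 at day 4, and 8.69, 17.4 and 7.63 CPM at day 16.

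ATRA against BMS753 at day 8 asks whether the early contrast lasts until neurons form. Pan-neuronal genes were higher under ATRA, with a median of 2.13 (13 of 16 higher, 0 lower; percentile 100). They included the neuronal tubulin Tubb3 (ENSMUSG00000062380) at 175 against 47.5 CPM, Dcx (ENSMUSG00000031285), a microtubule protein of migrating neurons, at 52.7 against 5.98, and the neurofilament gene Nefm (ENSMUSG00000022054) at 98.7 against 13.4. Motor and cholinergic genes had a median of 2.46 from 3 measured members and GABAergic genes 1.10 from 5. Primitive and parietal endoderm genes were higher (median 2.77, 11 of 11), as were muscle (2.13, 6 of 9), mesenchymal (1.497, 5 of 10), astroglia (1.28, 6 of 11 higher and 1 lower), retinoid response (1.43, 12 of 18 higher and 2 lower) and Hox genes (1.35 for groups 1 to 4 and 1.92 for groups 5 to 9, with 7 of 11 and 11 of 12 higher). Pluripotency genes had a median of −2.25 (1 of 18 higher, 16 lower). Neural progenitor genes lay at 0.13 (3 of 14 higher, 3 lower). The highest ratios were those of Ecm1 (ENSMUSG00000028108), an extracellular matrix gene (113-fold, 106 to 121), Lrrc7 (ENSMUSG00000028176, 60.6-fold), Tpbpa (ENSMUSG00000033834), a placental gene (936-fold, 365 to 3436, from 4 UMIs under BMS753), Cyp26b1 (25.4-fold) and the adhesion gene Alcam (ENSMUSG00000022636, 19.9-fold). Lower were Otx2 (ENSMUSG00000021848), a forebrain factor (43.1-fold, 34.4 to 54.9), Platr10 (18.3-fold), Pla2g1b (ENSMUSG00000029522, 13.3-fold), the pluripotency gene Utf1 (ENSMUSG00000047751, 11.02-fold) and Trh (11.4-fold). In all, 1711 genes were apart as higher and 430 as lower, or 1327 and 578 with TMM factors (shift −0.15). Within the Ftl1 kind it was 1627 and 325, and within the Ftl1-ps1 kind 1807 and 639. The pan-neuronal median was 2.48 and 1.11 in these kinds, and that of pluripotency −1.93 and −3.07.

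ATRA against BMS641+BMS961 at day 8 asks the same for the RARβ and RARγ agonists. Pan-neuronal genes had the highest median of the lists, 3.30 (15 of 16 higher, 0 lower), with Dcx at 52.7 against 1.05 CPM and the synaptic gene Syt1 (ENSMUSG00000035864) at 74.3 against 3.49. Proneural genes had a median of 2.26 (2 of 8 higher) and GABAergic genes 2.43 (3 of 5). Hox groups 1 to 4 had a median of 2.23 (9 of 10 higher) and groups 5 to 9 1.82 (11 of 13 higher). Retinoid response genes had a median of 1.59 (13 of 17 higher), astroglia genes 1.22 (5 of 10 higher, 1 lower) and neural progenitor genes 0.80 (5 of 12 higher, 1 lower). Pluripotency genes were lower (−1.81, 13 of 18). Visceral endoderm genes had a median of −0.36 (1 of 10 higher, 4 lower), which flips to 0.27 with equal weight per cell. By size, Ecm1 (209-fold, 193 to 228), Cyp26b1 (325-fold, 241 to 449), Fam155a (ENSMUSG00000079157, 40.5-fold), Dcx (50.4-fold, 42.8 to 59.7) and the neuropeptide gene Sst (ENSMUSG00000004366, 46.3-fold, 39.7 to 54.3) were higher. Cox6a2 (ENSMUSG00000030785), a muscle form of a respiratory subunit (75.9-fold), the stress gene Nupr1 (ENSMUSG00000030717, 17.0-fold), the myoblast fusion gene Mymx (ENSMUSG00000079471, 12.1-fold), the troponin gene Tnnt2 (ENSMUSG00000026414, 9.93-fold) and the apolipoprotein gene Apob (ENSMUSG00000020609, 8.91-fold) were lower. In all, 1217 genes were apart as higher and 269 as lower, or 839 and 405 with TMM factors (shift −0.25). Within the Ftl1 kind it was 1381 and 252 and the pan-neuronal median 3.93. Within the Ftl1-ps1 kind it was 1575 and 584 and the median 1.73, and without clusters 4 and 26 of the library labelled BMS641+BMS961 day 8 it was 1658 and 449 and the median 2.81.

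BMS753 was also set beside BMS641+BMS961 at day 8. Neural progenitor genes were higher under BMS753, with a median of 1.14 (8 of 14 higher, 1 lower; percentile 100), such as the notch target Hes5 (ENSMUSG00000048001) at 38.1 against 8.00 CPM. Pan-neuronal genes had a median of 1.12 (7 of 14 higher, 0 lower), Hox groups 1 to 4 1.20 (4 of 9 higher) and retinoid response genes 0.46 (5 of 15 higher, 1 lower). Visceral endoderm genes had a median of −1.29 (0 of 8 higher, 8 lower), primitive and parietal endoderm −0.998 (5 of 10 lower) and mesenchymal genes −1.78 (6 of 11 lower). Higher by size were Crabp2 (5.74-fold, 5.53 to 5.96), Dach1 (5.66-fold), Mir99ahg (ENSMUSG00000090386, 4.97-fold), the dorsal neural tube factor Pax3 (ENSMUSG00000004872, 4.98-fold, 4.64 to 5.36) and the netrin receptor Dcc (ENSMUSG00000060534, 4.61-fold). Lower were Pcdh11x (ENSMUSG00000034755, 40.9-fold), Tnnt2 (48.0-fold), Itm2a (ENSMUSG00000031239, 18.3-fold), Cox6a2 (66.3-fold) and Scand1 (ENSMUSG00000046229, 18.1-fold), which was also low, at 10.7 CPM, in the library labelled BMS641+BMS961 day 16. In all, 220 genes were apart as higher and 532 as lower, or 697 and 692 with equal weight per cell and 702 and 811 within the Ftl1 kind. Under BMS641+BMS961, 49.2% of cells lay in cluster 4, which held cells of that library nearly alone, with a median of 0.68% mitochondrial UMIs and no cell of the Ftl1-ps1 kind, and 4.34% in cluster 26. Without both clusters 121 genes were apart as higher and 133 as lower, the mesenchymal median turned to 0.62 and that of pluripotency from 0.44 to −0.20, whereas neural progenitor genes had 0.94 and visceral endoderm genes −1.84. Within the Ftl1-ps1 kind Pax3 stood at 19.3 against 7.49 CPM, Crabp2 at 134 against 34.8, Pcdh11x at 2.03 against 0.558 and Itm2a at 21.1 against 18.7. The mesenchymal median there was 0.66, the visceral endoderm median −2.11 and the neural progenitor median 0.85, with 91 genes apart as higher and 148 as lower.

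**Figure D4:**
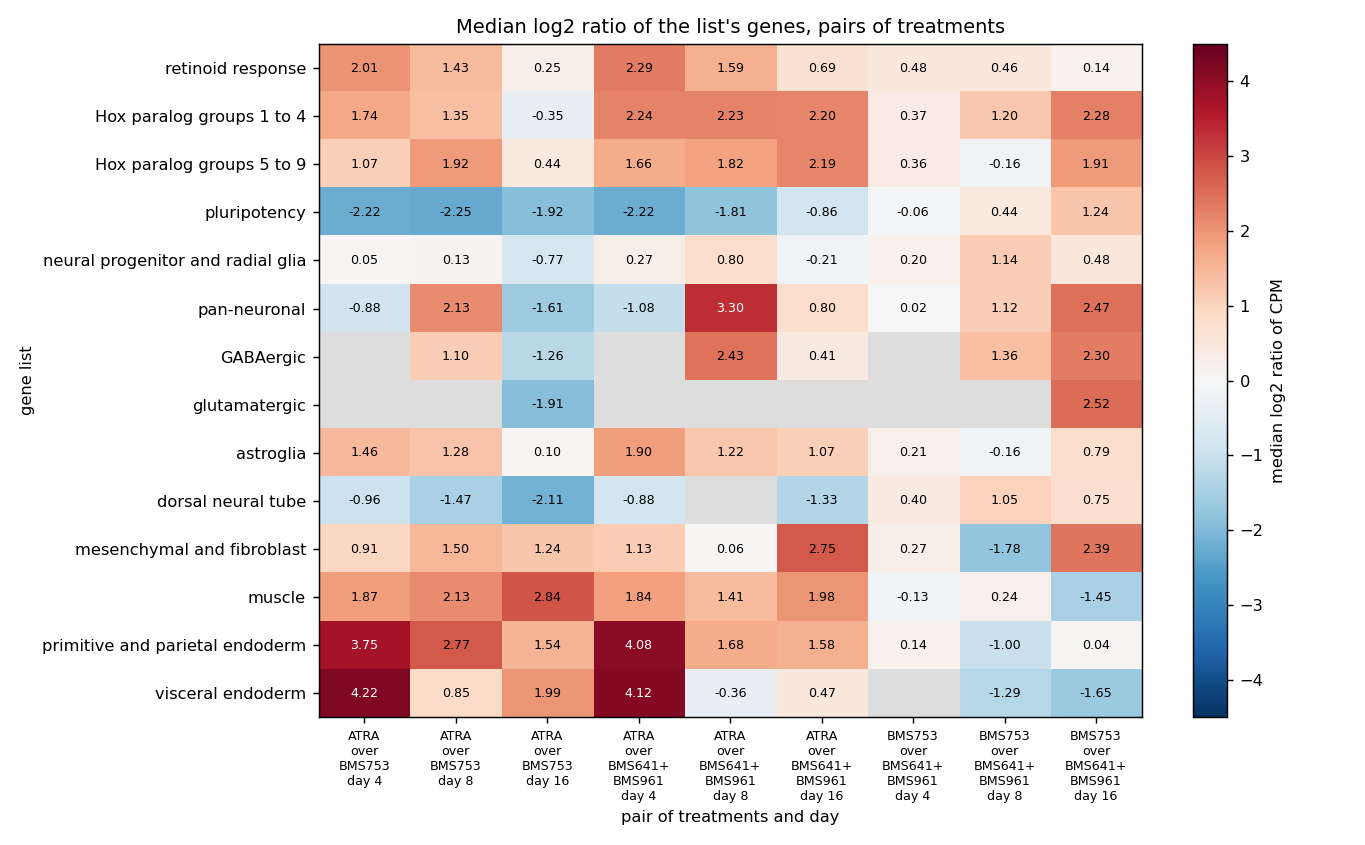
Median log2 ratio of CPM (colour) of 14 gene lists (vertical axis) in the 9 comparisons between treatments (horizontal axis), with grey where fewer than 3 members were measured. The pan-neuronal list is 2.13 for ATRA over BMS753 at day 8 and −1.61 at day 16, and its day 4 values (−0.88, and −1.08 over BMS641+BMS961) turn positive with equal weight per cell.

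At day 16, after the change to neuronal medium, ATRA against BMS753 asks which agonist left more neurons or astroglia. Pan-neuronal genes were now lower under ATRA, with a median of −1.61 (0 of 16 higher, 12 lower; percentile 0), such as Tubb3 at 85.8 against 323 CPM, Dcx at 17.1 against 97.2 and the growth cone gene Gap43 (ENSMUSG00000047261) at 84.6 against 264. Glutamatergic genes had a median of −1.91 (3 of 5 lower) and GABAergic genes −1.26 (5 of 9 lower), as for the glutamate transporter Slc17a6 (ENSMUSG00000030500) at 2.35 against 14.8 CPM and the GABA-synthesising enzyme Gad2 (ENSMUSG00000026787) at 5.38 against 28.0. The astroglia list lay at 0.10 with members on both sides (2 of 13 higher, 3 lower). Its intermediate filament gene Gfap (ENSMUSG00000020932) stood at 12.4 against 2.90 CPM and the fatty acid carrier Fabp7 (ENSMUSG00000019874) at 152 against 642. Dorsal neural tube genes had a median of −2.11 (2 of 6 lower), with the factor Zic1 (ENSMUSG00000032368) at 17.6 against 99.4 CPM, and proliferation genes one of −0.97 (11 of 22 lower). Pluripotency genes were lower (−1.92, 14 of 18). Muscle (2.84, 5 of 7), visceral endoderm (1.99, 6 of 11 higher, 1 lower), primitive and parietal endoderm (1.54, 9 of 11) and mesenchymal genes (1.24, 7 of 13) were higher. By size, the acute-phase gene Serpina3n (ENSMUSG00000021091, 582-fold, 405 to 869), Ftl1-ps1 (65.2-fold), the calcium-binding gene S100g (ENSMUSG00000040808, 35.0-fold), Gkn2 (59.4-fold) and Serpinb9b (ENSMUSG00000021403, 57.0-fold) were higher. Calcoco2 (ENSMUSG00000006056, 30.0-fold), Wfdc2 (ENSMUSG00000017723, 11.4-fold), Srrm4os (ENSMUSG00000086219, 13.6-fold), Dcc (9.21-fold, 8.98 to 9.45) and Pax3 (10.3-fold, 9.44 to 11.3) were lower. In all, 862 genes were apart as higher and 862 as lower, or 719 and 1074 with equal weight per cell. The library labelled ATRA day 16 held 80.2% cells of the Ftl1-ps1 kind and the other none. Among Ftl1 kind cells 1088 genes were apart as higher and 766 as lower. There the pan-neuronal median was −0.81 (0 of 16 higher, 4 lower), that of glutamatergic genes −1.44, of astroglia genes 0.40, of mesenchymal genes 0.50, of pluripotency −3.44 and of muscle 3.86, and Serpina3n stood at 24.2 against 0.211 CPM.

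ATRA against BMS641+BMS961 at day 16 asks the same of the RARβ and RARγ agonists. Mesenchymal genes had a median of 2.75 (12 of 13 higher, 0 lower; percentile 100), such as the proteoglycan Dcn (ENSMUSG00000019929) at 1128 against 16.6 CPM (67.8-fold, 65.0 to 70.7) and the collagen gene Col3a1 (ENSMUSG00000026043) at 1673 against 87.3. Hox groups 5 to 9 had a median of 2.19 (10 of 14 higher, 0 lower) and groups 1 to 4 2.20 (5 of 5). Pan-neuronal genes had a median of 0.80 (6 of 16 higher, 0 lower), a direction that flips to −0.27 with equal weight per cell. Astroglia genes had a median of 1.07 (6 of 13 higher, 1 lower), with the transcription factor Nfib (ENSMUSG00000008575) at 508 against 62.6 CPM and Gfap at 12.4 against 3.46. Primitive and parietal endoderm genes had a median of 1.58 (9 of 11 higher) and muscle genes 1.98 (5 of 8 higher, 2 lower). Proliferation genes were lower (−1.20, 16 of 22), and pluripotency genes had a median of −0.86 (7 of 18 lower, 1 higher). By size, Serpina3n (364-fold), Ftl1-ps1 (82.9-fold), Dcn, the matrix gene Fmod (ENSMUSG00000041559, 212-fold) and the uroplakin Upk1b (ENSMUSG00000049436, 145-fold) were higher. Wfdc2 (11.002-fold), Adgrv1 (ENSMUSG00000069170, 9.61-fold), the chromatin gene Hmga1 (ENSMUSG00000046711, 9.93-fold), Calca (8.69-fold) and the histone gene Hist1h2ap (ENSMUSG00000094777, 6.58-fold) were lower. In all, 1783 genes were apart as higher and 488 as lower, or 1389 and 717 with TMM factors (shift −0.16) and 1393 and 748 with equal weight per cell. Of ATRA's assigned cells 80.2% were of the Ftl1-ps1 kind, and none of the other library's. Within the Ftl1 kind it was 2280 and 537, with medians of 1.64 for pan-neuronal, 2.20 for mesenchymal, 1.49 for astroglia, 2.48 for Hox groups 5 to 9 and −2.06 for pluripotency genes.

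BMS753 against BMS641+BMS961 at day 16 compares 2 libraries with no cell of the Ftl1-ps1 kind. Pan-neuronal, glutamatergic and GABAergic lists were higher under BMS753. Pan-neuronal genes had a median of 2.47 (15 of 16 higher, 0 lower; percentile 100), with Tubb3 at 323 against 54.0 CPM, glutamatergic genes 2.52 (3 of 5) and GABAergic genes 2.30 (5 of 8), with Slc17a6 at 14.8 against 0.962 CPM and Gad2 at 28.0 against 8.79. Astroglia genes had a median of 0.79 (4 of 12 higher, 1 lower; percentile 99.9), with Fabp7 at 642 against 124 CPM, the glutamate transporter Slc1a2 (ENSMUSG00000005089) at 28.9 against 3.32 and Apoe (ENSMUSG00000002985) at 1542 against 1603. Mesenchymal genes had a median of 2.39 (8 of 11 higher), Hox groups 1 to 4 2.28 (4 of 7), groups 5 to 9 1.91 (10 of 12) and pluripotency genes 1.24 (12 of 18 higher, 1 lower). Visceral endoderm genes were lower (−1.65, 6 of 8), and so were muscle genes (−1.45, 4 of 5), while mesoderm genes had a median of −0.98 (2 of 5 lower). By size, Sst (39.1-fold, 34.0 to 45.0), the neuregulin Nrg3 (ENSMUSG00000041014, 19.6-fold), the collagen Col1a2 (ENSMUSG00000029661, 20.1-fold, 18.6 to 21.8), Lingo2 (ENSMUSG00000045083, 17.9-fold) and Pcsk1n (ENSMUSG00000039278, 18.6-fold) were higher. T (82.7-fold, 64.8 to 107), the mesoderm factor Hand1 (ENSMUSG00000037335, 205-fold, 131 to 342), Ptgds (ENSMUSG00000015090, 27.5-fold), Fgf8 (33.4-fold) and Apoc2 (ENSMUSG00000002992, 17.1-fold) were lower. In all, 1325 genes were apart as higher and 181 as lower, with a TMM shift of −0.20.

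Classes at day 16 were compared to ask whether a treatment's cells differed within them. The astroglia-like cells of the 3 libraries came from the same cluster. Those under ATRA stood higher than those under BMS753 for astroglia genes, with a median of 1.39 (11 of 18 higher, 0 lower), and for Hox groups 5 to 9 (1.56, 11 of 15). Dorsal neural tube genes were lower in them (−1.50, 1 of 8 higher, 5 lower). The oligodendrocyte lineage factor Olig1 (ENSMUSG00000046160) was 50.2-fold higher (31.6 to 84.5) and A2m (ENSMUSG00000030111) 261-fold (71.3 to 2174, from 2 UMIs), whereas Cyp26b1 was 85.8-fold lower (33.4 to 315), the dorsal factor Msx3 (ENSMUSG00000025469) 53.6-fold (20.8 to 197) and the ephrin receptor Epha6 (ENSMUSG00000055540) 23.7-fold (14.7 to 40.8). Against BMS641+BMS961 the astroglia-like cells of ATRA had an astroglia median of 1.72 (13 of 18 higher, 0 lower) and a median of 1.86 for Hox groups 1 to 4 (8 of 8). Nrg3 was 100-fold higher there (27.6 to 829, from 2 UMIs) and Hoxb5os (ENSMUSG00000085645) 142-fold (25.2 to 5610, from 1 UMI), whereas Cyp26b1 was 27.2-fold, Adgrv1 8.52-fold (7.29 to 10.0) and Cbln1 (ENSMUSG00000031654) 10.1-fold lower. Between BMS753 and BMS641+BMS961 the astroglia median was 0.21 (1 of 16 higher, 3 lower). Scand1 (21.7-fold), Zfp804b (ENSMUSG00000092094, 11.1-fold) and Pcsk1n (12.2-fold) were higher under BMS753, and Krt8 (ENSMUSG00000049382, 7.66-fold) and Gfap (6.07-fold, 4.92 to 7.48) lower. Scand1 was low in all 10 clusters of the library labelled BMS641+BMS961 day 16 with enough cells (7.53 to 12.1 CPM), so its fold here and in the classes below belongs to the library and not to a class. Genes apart in astroglia-like cells numbered 674 higher and 450 lower for ATRA over BMS753, 1045 and 403 for ATRA over BMS641+BMS961, and 458 and 145 for BMS753 over BMS641+BMS961. The astroglia medians of ATRA within the Ftl1 kind were 1.67 and 1.82, and the counts 693 and 600, 1021 and 494, and 450 and 144.

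In neuron-like cells, which came mostly from cluster 8 (97.4%, 84.0% and 80.9% of them under ATRA, BMS753 and BMS641+BMS961), the pan-neuronal medians were near 0. They were −0.19 for ATRA over BMS753, 0.17 for ATRA over BMS641+BMS961 and 0.34 for BMS753 over BMS641+BMS961. Glutamatergic genes were lower in the neuron-like cells of ATRA than of BMS753 (−1.07, 4 of 7 lower), and GABAergic genes higher under BMS753 than under BMS641+BMS961 (1.29, 7 of 10). ATRA against BMS753 had the calcium-binding gene S100a6 (ENSMUSG00000001025, 56.7-fold, 44.9 to 72.6), Pga5 (110-fold) and Anxa1 (ENSMUSG00000024659, 58.1-fold) higher, and the commissural guidance receptor Robo3 (ENSMUSG00000032128, 81.0-fold), Lhx2 (ENSMUSG00000000247, 130-fold, 35.9 to 1078, from 2 UMIs) and Zic4 (ENSMUSG00000036972, 22.3-fold) lower. Against BMS641+BMS961, Hoxc8 (ENSMUSG00000001657, 40.3-fold), Dcn (35.0-fold) and Ftl1-ps1 were higher and Robo3 (65.9-fold), the neuropeptide Vip (ENSMUSG00000019772, 60.3-fold) and Crabp2 (24.2-fold) lower. Free RNA may add to Dcn, which was 14.4-fold higher within the Ftl1 kind and 67.8-fold over the whole libraries, and the mesenchymal gene Col1a1 (ENSMUSG00000001506) was found in 5.04% of ATRA's neuron-like cells against 0.997%. BMS753 had Scand1 (18.0-fold), Hoxa2 (ENSMUSG00000014704, 29.3-fold, 8.08 to 243, from 2 UMIs) and Hoxa5 (9.88-fold) higher than BMS641+BMS961, and Vip (19.3-fold), Krt18 (ENSMUSG00000023043, 15.7-fold) and Trh (14.4-fold) lower. The counts of genes apart in neuron-like cells were 688 higher and 376 lower, 1180 and 662, and 418 and 460, in the order of the medians, or 708 and 466, 1298 and 857, and 458 and 467 within the Ftl1 kind.

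Mesenchymal-like cells made up 49.1% of cells under ATRA at day 16, 34.9% under BMS753 and 9.08% under BMS641+BMS961. Under ATRA they were 27.4% of the Ftl1 kind and 55.4% of the Ftl1-ps1 kind. They came from cluster 3 under ATRA (98.8%) and from cluster 5 in the other libraries (99.4% in each). ATRA against BMS753 had Serpina3n (211-fold, 132 to 362), Ftl1-ps1 (121-fold) and Serpinb7 (ENSMUSG00000067001, 217-fold) higher and the sarcoglycan gene Sgcz (ENSMUSG00000039539, 36.7-fold, 30.3 to 44.8), Mdga2 (ENSMUSG00000034912, 24.8-fold) and the crest factor Tfap2b (ENSMUSG00000025927, 37.6-fold) lower. Against BMS641+BMS961, Ftl1-ps1 (113-fold), Serpina3n (308-fold, 85.2 to 2542, from 2 UMIs) and Itgbl1 (ENSMUSG00000032925, 72.6-fold) were higher and Sgcz (58.3-fold), Cntn3 (ENSMUSG00000030075, 27.5-fold) and Galntl6 (ENSMUSG00000096914, 21.4-fold) lower. BMS753 against BMS641+BMS961 had Scand1 (13.5-fold), Kcnh5 (ENSMUSG00000034402, 16.2-fold) and Sostdc1 (ENSMUSG00000036169, 7.39-fold) higher and Pdlim3 (ENSMUSG00000031636, 16.5-fold), the RNA-binding gene Lin28a (ENSMUSG00000050966, 11.6-fold) and the factor Isl1 (ENSMUSG00000042258, 10.1-fold) lower. Genes apart were 494 higher and 678 lower for ATRA over BMS753 (703 and 492 with TMM factors), 738 and 831 for ATRA over BMS641+BMS961 (1166 and 552), and 317 and 223 for BMS753 over BMS641+BMS961. These were 640 and 591, 924 and 776, and 321 and 228 within the Ftl1 kind. Pluripotent-like cells came from cluster 28 under ATRA (89.1%) and from cluster 9 under BMS753 and BMS641+BMS961 (99.6% and 97.7%), and had 333 genes higher and 394 lower, 609 and 293 (448 and 383 with TMM factors), and 165 and 46. Of ATRA's 669 such cells 621 were of the Ftl1-ps1 kind, and the 47 of the Ftl1 kind gave 291 and 605 against BMS753, with 290 genes shared with the pooled calls, and 488 and 357 against BMS641+BMS961. Visceral endoderm-like cells had 787 and 344, 773 and 289 (599 and 366 with TMM factors), and 335 and 359, or 869 and 412, 831 and 331, and 332 and 362 within the Ftl1 kind. At resolution 2 this class fell from 959, 515 and 989 cells under ATRA, BMS753 and BMS641+BMS961 to 82, 68 and 204, and the counts were 889 and 732, 969 and 617, and 404 and 312. In them the gut genes Pyy (ENSMUSG00000017311), at 68.2 against 0 CPM, and Fabp2 (ENSMUSG00000023057, 105-fold, 57.1 to 219) were higher under ATRA than under BMS753. ATRA over BMS641+BMS961 had 473 higher and 340 lower in nascent mesoderm-like cells. That sets one kind against the other, since 837 of ATRA's 855 such cells were of the Ftl1-ps1 kind and none of the other library's. Only 5 were of the Ftl1 kind, and at resolution 2, with 171 cells under ATRA, the counts were 589 and 426. Smooth muscle-like cells had 927 and 303 (983 and 380 within the Ftl1 kind), where ATRA's came from clusters 13 (52.8%) and 32 (47.2%), and at resolution 2, with 616 cells under ATRA in place of 180, they had 1393 and 365.

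**Figure D5:**
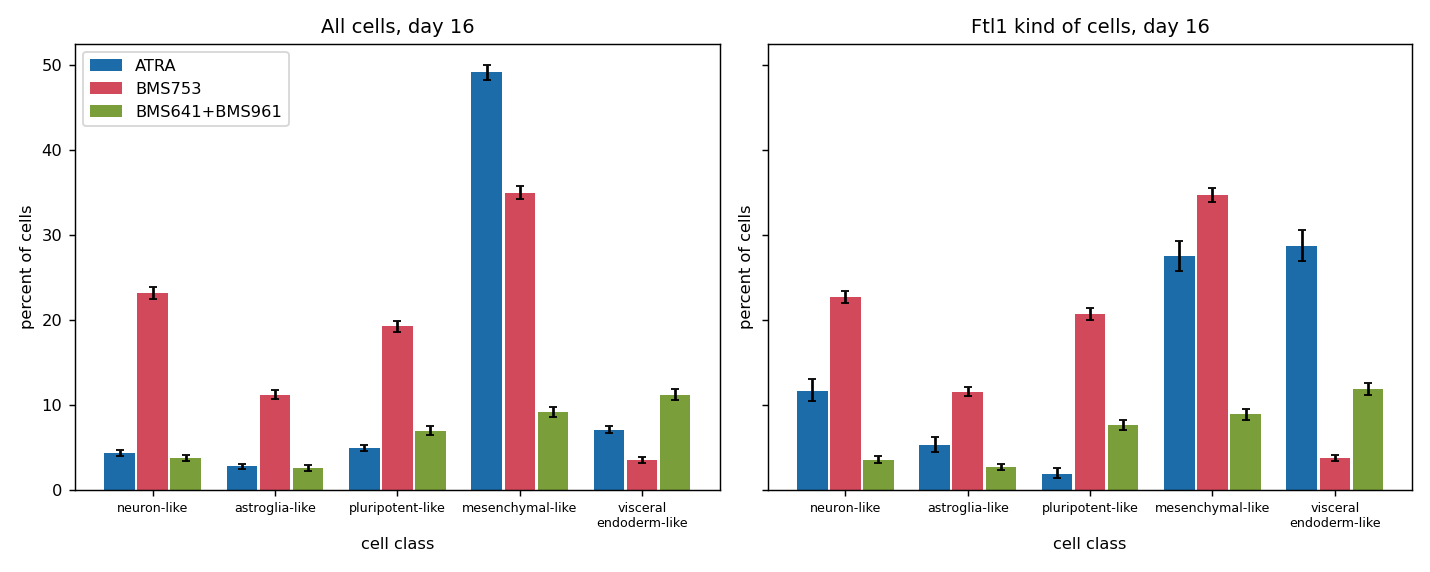
Percent of cells (vertical axis) in 5 classes at day 16 under each treatment (bars, Clopper-Pearson 95% intervals), over all cells on the left and over cells of the Ftl1 kind on the right. Neuron-like cells are 4.29%, 23.1% and 3.71% over all cells and 11.7%, 22.7% and 3.51% within the Ftl1 kind for ATRA, BMS753 and BMS641+BMS961.

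Shares of cells with a UMI at day 16 followed single genes. After thinning, Tubb3 was found in 4.22%, 25.5% and 7.57% of cells under ATRA, BMS753 and BMS641+BMS961, against 1.16%, 5.31% and 2.28% of visceral endoderm-like cells, which should lack it. In the Ftl1 kind it stood at 178, 324 and 53.8 CPM. The glial glutamate transporter Slc1a3 (ENSMUSG00000005360) was found in 14.3%, 10.6% and 5.26% of cells, against 5.23%, 1.90% and 2.77% of pluripotent-like cells. Under ATRA only 187 cells with it were astroglia-like. Median depth before thinning was 8253, 7152.5 and 11871 UMIs, with 30724, 14394 and 14541 in the visceral endoderm-like and 14902, 16175 and 14957.5 in the pluripotent-like cells. The 2000 UMI limit left out 419, 532 and 511 cells. Within astroglia-like cells, Gfap was found in 28.4% (23.8 to 33.4) under ATRA, 1.97% (1.35 to 2.77) under BMS753 and 12.1% (8.10 to 17.1) under BMS641+BMS961, and in 20.5%, 2.03% and 11.9% of those of the Ftl1 kind, against 0.299%, 0.351% and 0.326% of pluripotent-like cells. The water channel Aqp4 (ENSMUSG00000024411) was found in 10.9%, 1.54% and 3.57% of astroglia-like cells, and in 0 of 669, 2845 and 614 pluripotent-like cells (upper limits 0.550%, 0.130% and 0.599%). The neuronal gene Stmn2 (ENSMUSG00000027500) was found in 2.51%, 33.6% and 8.04% of astroglia-like cells, against 1.05%, 6.496% and 6.63% of visceral endoderm-like cells. Astroglia-like cells were shallower (medians 8492, 6520 and 6341.5 UMIs), so free RNA of Stmn2 may weigh more in them. Whether it makes up the 33.6% was not tested. At day 4, Rarb was found in 42.9% (42.0 to 43.8), 3.74% (3.24 to 4.29) and 0.636% (0.449 to 0.876) of cells after thinning, and in 63.2%, 21.3% and 3.05% without it. In pluripotent-like cells the thinned shares were 13.5%, 0.802% and 0.510%, at median depths of 10569.5, 11081 and 6363 UMIs against 7916, 11612.5 and 7899.5 over all cells, and 5292, 120 and 97 cells were left out.

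Days were also compared within a treatment. Under ATRA, pan-neuronal genes were higher at day 8 than at day 4 (3.10, 15 of 16 higher), and for day 16 over 8 their median was −0.47 (5 of 16 lower). Retinoid response genes had medians of −0.42 for day 8 over 4, −1.67 for day 16 over 8 and −2.68 for day 16 over 4 (0 of 18 higher, 11 lower). Mesenchymal (3.84, 12 of 13) and astroglia genes (1.77, 8 of 14 higher, 1 lower) were higher at day 16 than at day 4. By size these were the matrix genes Mgp (ENSMUSG00000030218, 1528-fold, 1156 to 2066), Lum (ENSMUSG00000036446, 923-fold), Postn (ENSMUSG00000027750, 717-fold) and Lox (ENSMUSG00000024529, 4249-fold, 1821 to 13088, from 5 UMIs) and Ecrg4 (ENSMUSG00000026051, 323-fold). Stra8 (1463-fold, 1154 to 1885), Cyp26b1 (110-fold), the atrial light chain Myl7 (ENSMUSG00000020469, 68.1-fold), Cxcl10 (65.2-fold) and Calcoco2 (105-fold) were lower. In all, 1268 genes were apart as higher and 727 as lower at day 16 over day 4. Within the Ftl1 and Ftl1-ps1 kinds this was 2220 and 472, and 1164 and 1139, with pan-neuronal medians of 2.63 and 1.54, retinoid response medians of −2.04 and −2.63, and primitive and parietal endoderm at −0.33 and 1.90 where the pooled median was 0.40. Mgp was higher in both, and Stra8 (12.8 to 0.525 CPM and 755 to 0.228) and Cxcl10 (652 to 1.56 and 11.5 to 4.51) lower. Day 8 over day 4 had 695 and 194, or 2088 and 685 within the Ftl1 kind and 730 and 450 within the Ftl1-ps1 kind. Day 16 over day 8 had 801 and 584, or 779 and 1104 with equal weight per cell, and 1153 and 732, and 841 and 778 within the kinds.

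Under BMS753, pan-neuronal genes were higher late, with medians of 0.47 for day 8 over 4, 2.88 for day 16 over 8 (16 of 16 higher) and 3.69 for day 16 over 4. Astroglia genes had medians of 0.35, 2.00 (7 of 12 higher, 0 lower) and 2.56 (9 of 12 higher, 1 lower), and mesenchymal genes −0.13, 3.93 and 4.46. GABAergic genes had a median of 3.08 (6 of 8) and glutamatergic genes 2.18 (3 of 5) for day 16 over 4. Retinoid response genes lay at 0.09, −1.52 and −0.44, the last of which flips to 0.11 with equal weight per cell. Fabp7 (608-fold, 490 to 765), the protocadherin Pcdh9 (ENSMUSG00000055421, 168-fold), the synaptic adhesion gene Nlgn1 (ENSMUSG00000063887, 329-fold), Spink1 (ENSMUSG00000024503, 280-fold) and Dcc (111-fold) were higher at day 16 than at day 4. Tcf15 (ENSMUSG00000068079, 86.1-fold), Pla2g1b (53.1-fold), Halr1 (ENSMUSG00000085412, 44.0-fold), Cda (ENSMUSG00000028755, 42.3-fold) and Hoxb1 (ENSMUSG00000018973, 143-fold) were lower. In all, 2268 genes were apart as higher and 487 as lower for day 16 over 4 (1434 and 1299 with TMM factors), 369 and 228 for day 8 over 4 (224 and 435, or 635 and 226 with equal weight per cell) and 1871 and 447 for day 16 over 8 (1459 and 708). TMM shifts were −0.41, −0.24 and −0.17. Day 8 held 57.8% cells of the Ftl1-ps1 kind and the other days none, and within the Ftl1 kind the counts were 2253 and 484, 330 and 205, and 1783 and 386.

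Under BMS641+BMS961, visceral endoderm genes were higher at day 8 than at day 4 (4.92) and at day 16 than at day 4 (4.57, 8 of 8), and primitive and parietal endoderm genes were too (2.49 and 2.87, 10 of 10 at day 16). Pan-neuronal genes had medians of −0.96 for day 8 over 4 (6 of 10 lower), 1.52 for day 16 over 8 (10 of 15 higher) and 1.03 for day 16 over 4 (5 higher, 1 lower). Astroglia genes had medians of 0.64, 1.06 and 2.14 (6 of 10 higher) and pluripotency genes −0.09, −1.26 and −1.14 (1 of 18 higher, 10 lower). Retinoid response genes lay at 0.22, −0.60 and −0.15. Spink1 (503-fold), the thyroid hormone carrier Ttr (ENSMUSG00000061808, at least 5091-fold), S100g (167-fold), Rbp4 (ENSMUSG00000024990, 76.5-fold) and Fabp7 (72.8-fold) were higher at day 16 than at day 4. Halr1 (82.2-fold), Pla2g1b (27.7-fold), the myosin light chain gene Mylpf (ENSMUSG00000030672, 19.4-fold), Dppa2 (ENSMUSG00000072419, 18.3-fold) and Scand1 (16.0-fold) were lower. In all, 1319 genes were apart as higher and 522 as lower for day 16 over 4 (832 and 995 with TMM factors), 1060 and 298 for day 8 over 4 (673 and 642) and 629 and 558 for day 16 over 8 (994 and 512 with equal weight per cell). TMM shifts were −0.32, −0.26 and −0.06. Among Ftl1 kind cells the counts were 1299 and 524, 1264 and 499, and 752 and 616. Without clusters 4 and 26 of day 8, day 8 over 4 had 759 and 224 and the mesenchymal median turned from 1.63 to −0.55.

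Across days, 347 genes were higher and 108 lower under ATRA than under BMS753 at all 3 days, and 43 were apart in opposite directions at days 4 and 16. Against BMS641+BMS961 these were 338, 43 and 40. The pooled kinds may add to these counts. Between BMS753 and BMS641+BMS961, 6 genes were higher at all 3 days (Adgrl3, Dach1, Erbb4, Mir99ahg, Ptprz1 and Rarb) and 0 lower. At day 4, 1724 of 9633 genes were apart as higher under ATRA than in both other libraries. Overlap was built in by the shared ATRA library and the others' correlation of 0.992. By the same rule BMS753 was apart above both others for 6 genes and BMS641+BMS961 for 11. At day 16, 690 of 10616 genes were apart as higher than in both others under ATRA, 476 under BMS753 and 64 under BMS641+BMS961, and 222, 83 and 698 as lower than in both.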

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

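The tests in this part were chosen after the results they bear on were seen, and set technical explanations against biological ones. No difference between days was itself tested, since each rests on 1 library per group.

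Cells of 5 libraries fell into 2 kinds by their UMIs on Ftl1 and Ftl1-ps1, and the kinds parted other genes as well. Reads shared between the near-identical copies would leave other genes alone, but 5 of the 6 genes that part the kinds in all 11 groups of cells compared within clusters at day 8 did so the same way in all 4 at day 16 under ATRA. A state that cells enter under retinoids is argued against at day 8. There 90.0% of the clusters with enough cells, counted per library (18 of 20, 68.3 to 98.8), held at least 10% of each kind. The interval takes them as independent, although the same cluster can count in more than 1 library, so its limits are a rough guide. Under ATRA at day 4 (20%, 1 of 5) and day 16 (50%, 4 of 8) such a state cannot be told apart. The clusters there are too few, and most at day 4 held 1 kind nearly alone. Whether a second cell line without Hprt transcripts is the source cannot be told apart, since the low Hprt of the Ftl1-ps1 kind (at most 4.49% of the level in the Ftl1 kind within the day 16 clusters) is what prompted that explanation. The labels name 1 line for all libraries, so the origin of the kinds stays open.

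Few cells lay between the kinds, with 2 under ATRA at day 4 where doublets of 1 capture would give about 1165, and 21 against 458 under ATRA at day 16. In 1 capture, free RNA of one kind reaches the other, yet Ftl1-ps1 took 0.360% of the Ftl1 and Ftl1-ps1 UMIs in Ftl1 kind cells under ATRA at day 4 and 0.685% at day 16, no more than the 0.799% seen without the other kind. Those shares argue against 1 capture for these libraries, which may be put together from separate ones. At day 8 the shares were 2.496% under ATRA, 3.54% under BMS753 and 2.36% under BMS641+BMS961 outside clusters 4 and 26, as 1 capture needs. Yet 83, 210 and 137 cells lay between where 1 capture of each whole library would give about 115, 338 and 480. The share was 0.360% in cluster 4 of the library labelled BMS641+BMS961 day 8, which argues against 1 capture with the rest of it, whereas for cluster 26 (0.694%, 0.582 to 0.822) this cannot be told apart, since its interval holds the 0.799%.

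Pan-neuronal genes were higher in ATRA than in BMS753 at day 8 (median log2 ratio 2.13) and lower at day 16 (−1.61). This turn stood out. The Ftl1-ps1 kind is not the whole cause, since the day 16 median within the Ftl1 kind was −0.81. TMM factors gave −1.56 but shift each log2 ratio by 0.04, too little to judge scaling. Fewer neuron-like cells and not a lower level in them may account for the −1.61, since within neuron-like cells the median was −0.19. Yet the class was defined by genes of this sort and its glutamatergic genes were lower (−1.07). Seeding density, which differs with treatment and day, and days in neuronal medium, which differ with day only, were not tested.

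Pan-neuronal genes also turned between ATRA and BMS641+BMS961, from −1.08 at day 4 (0.13 with equal weight per cell and 0.11 within the Ftl1 kind) to 3.30 at day 8. Mesenchymal genes turned between BMS753 and BMS641+BMS961, from −1.78 at day 8 (0.62 without clusters 4 and 26) to 2.39 at day 16.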

How the results depend on the processing

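The alternatives marked as added were chosen after seeing the data. No paired analysis was possible with 1 library per group, and no test was run. All 18 totals of genes apart, higher and lower together, stayed within 1.5 times of their value with all deposited barcodes and the stricter filter. They also did with TMM factors, cells with at least 2000 UMIs and doublets removed by score. So did 17 totals with equal weight per cell, 16 within the Ftl1 kind and 15 with a floor of 5 CPM. The split into higher and lower was not held to that limit. With TMM factors it moved further, as at day 4 for ATRA over each other treatment. A kept total need not hold the same genes. Within the Ftl1 kind, 60.2% of the pooled calls for ATRA over BMS641+BMS961 at day 4 were shared. Of 4402 list medians under an alternative 38 (0.863%) were counted as reversed. Only medians outside the 95% range of random lists could be, so other changes of sign are not among them. Of the 4364 others, 3922 moved by less than the spread of random lists (one side of their 95% range), 172 moved further up and 270 further down. Beside the shares given below, 586 of 781 class shares stayed within their counting interval, 102 were higher and 93 lower. Over these alternatives astroglia-like cells at day 16 ranged from 2.10% to 5.29% under ATRA, 10.96% to 11.9% under BMS753 and 2.49% to 2.69% under BMS641+BMS961. The missing replicate, and depth for genes under 10 CPM, limit all of these results. The cause was not tested for any value below that moved or reversed, apart from those whose fold limit, floor or thinning is itself stricter or looser.

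Without clusters 4 and 26 of the library labelled BMS641+BMS961 day 8, genes apart between BMS753 and BMS641+BMS961 at day 8 fell from 752 to 254. Pluripotency there turned to −0.20 and mesenchymal genes to 0.62. For BMS641+BMS961, day 8 over 4, mesenchymal genes turned to −0.55, dorsal neural tube genes from −0.99 to 0.14, proliferation genes from −0.42 to 0.14 and cholesterol synthesis genes from −0.19 to 0.13. Proliferation genes for day 16 over 8 turned from 0.36 to −0.15.

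Within the Ftl1 kind, genes apart were 1513 for BMS753 over BMS641+BMS961 at day 8 and 2773, from 889, for ATRA day 8 over 4. Pan-neuronal genes at day 4 turned to 0.15 for ATRA over BMS753 and 0.11 over BMS641+BMS961, and dorsal neural tube genes to 0.47 for the latter. For ATRA day 8 over 4, primitive and parietal endoderm genes turned from 0.39 to −0.72 and hypoxia genes from 0.50 to −0.0774, and for day 16 over 4 the endoderm genes turned to −0.33. At day 16 astroglia-like cells were 5.29% and neuron-like cells 11.7% under ATRA, and pluripotent-like cells 1.88%, 20.7% and 7.56% under ATRA, BMS753 and BMS641+BMS961.

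Within the Ftl1-ps1 kind, genes apart were 239 for BMS753 over BMS641+BMS961 at day 8, where pluripotency turned to −0.0599 and mesenchymal genes to 0.66. For ATRA day 8 over 4, pluripotency turned from 0.26 to −1.26 and cholesterol synthesis from 0.21 to −0.30, and for day 16 over 8 visceral endoderm genes turned from 0.93 to −0.95. At day 16 astroglia-like, neuron-like and pluripotent-like cells were 2.10%, 1.84% and 6.09% under ATRA.

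Pluripotent-like cells at day 16 were 19.96% under BMS753 and 7.57% under BMS641+BMS961 at resolution 0.5, 19.95% under BMS753 with the stricter filter, 21.4% and 8.23% after clustering thinned cells, and 5.56%, 20.5% and 7.53% under ATRA, BMS753 and BMS641+BMS961 with doublets removed by score. Neuron-like cells were 3.80% under ATRA and 22.0% under BMS753 at resolution 2. With doublet calls kept in, BMS753 had 11.9% astroglia-like, 25.5% neuron-like and 18.1% pluripotent-like cells.

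At 4-fold, genes apart for ATRA over BMS753, ATRA over BMS641+BMS961 and BMS753 over BMS641+BMS961 were 615, 739 and 6 at day 4 (2346, 2754 and 62 at 2-fold), 611, 503 and 138 at day 8 (2141, 1486 and 752), and 416, 648 and 532 at day 16 (1724, 2271 and 1506). For day 8 over 4, 16 over 8 and 16 over 4 they were 316, 414 and 777 under ATRA (889, 1385 and 1995), 108, 854 and 1083 under BMS753 (597, 2318 and 2755), and 265, 294 and 474 under BMS641+BMS961 (1358, 1187 and 1841). With a floor of 50 CPM, in the same orders, they were 885, 1035 and 14, then 791, 499 and 231, then 637, 871 and 477 between treatments, and 275, 464 and 741, then 161, 743 and 946, then 444, 306 and 537 between days. With that floor within classes, in the order of the treatment pairs, they were 370, 458 and 174 in astroglia-like, 381, 539 and 182 in mesenchymal-like, 361, 646 and 270 in neuron-like, 173, 254 and 63 in pluripotent-like and 363, 366 and 216 in visceral endoderm-like cells, and for ATRA over BMS641+BMS961 221 in nascent mesoderm-like and 384 in smooth muscle-like cells. With a floor of 5 CPM they were 98 for BMS753 over BMS641+BMS961 at day 4, 901 for BMS753 day 8 over 4 and 1788 for BMS641+BMS961 day 16 over 8.

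With equal weight per cell, genes apart for BMS753 over BMS641+BMS961 at day 8 were 1389. Pan-neuronal genes turned to 0.25 for ATRA over BMS753 and 0.13 over BMS641+BMS961 at day 4, and to −0.27 over BMS641+BMS961 at day 16. Dorsal neural tube genes (day 4) and visceral endoderm genes (day 8) turned to 0.25 and 0.27 for ATRA over BMS641+BMS961. The median of pluripotency, ATRA day 8 over day 4, turned to −0.065. Under ATRA visceral endoderm turned to −0.45 (day 16 over 8), and for day 16 over 4 primitive and parietal endoderm turned to −0.39, visceral endoderm to −0.50 and endothelial genes to −0.14. Retinoid response genes under BMS753 (day 16 over 4) turned to 0.11, and immediate early genes under BMS641+BMS961 (day 16 over 8) to 0.0917.

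With no floor for members, ependymal genes for BMS753 over BMS641+BMS961 turned to 0.0078 at day 8 and 0.0083 at day 16, and surface epithelium genes to 0.13 at day 16. GABAergic genes turned to 0.12 for ATRA day 16 over 8, surface epithelium genes to 0.18 and 0.55 for BMS753 day 16 over 8 and over 4, and proneural and mesoderm genes to 0.15 and 0.074 for BMS641+BMS961 day 8 over 4.

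Without thinning, Tubb3 was found in 10.52%, 41.0% and 25.2% of day 16 cells under ATRA, BMS753 and BMS641+BMS961 and Slc1a3 in 35.8%, 24.8% and 24.5%. Thinned to 1000 UMIs these were 2.87%, 19.7% and 4.97%, and 8.44%, 6.24% and 2.53%. Of 204 other shares with a UMI under these alternatives, 32 stayed within their counting interval.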

Other observations

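The kinds, naming threshold and genes of this part were chosen after seeing the data. The kinds under ATRA at days 4 and 16 may be separate captures, to which gaps there may belong instead. Under ATRA at day 4 the kinds differed in retinoid and signalling genes. Stra8, the meiosis gene, stood at 755 CPM in the Ftl1-ps1 kind and 12.8 CPM in the Ftl1 kind. Gkn2 stood at 0.0215 and 488 CPM in that order, and Cxcl10 at 11.5 and 652 CPM. The shallow cluster 6, with no Ftl1-ps1 kind cell, made up 4730 of the 6272 Ftl1 kind cells there. Under ATRA at day 8 these genes were close, with Stra8 at 92.4 and 112 CPM, Gkn2 at 17.8 and 10.7 and Cxcl10 at 6.23 and 6.72. Gkn2 was apart again under ATRA at day 16 (11.6 and 128), and Stra8 the same way as at day 4 under BMS641+BMS961 at day 8 (160 and 39.1). Cyp26b1 was close in the kinds at day 4, at 169 and 173 CPM. At day 8 under ATRA, smooth muscle-like cells were 8.49% of the Ftl1 kind and 42.1% of the Ftl1-ps1 kind, and primitive or parietal endoderm-like cells 17.5% and 15.6%. The Y-linked helicase gene Ddx3y (ENSMUSG00000069045) stood at 41.1 CPM in the Ftl1 kind and 2.99 in the Ftl1-ps1 kind under ATRA at day 4, at 38.4 and 37.0 at day 8, and at 48.5 and 15.5 at day 16.

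Other gene groups also differed between the treatments. Immediate early and stress genes were higher under ATRA at day 16, with medians of 1.72 against BMS753 (9 of 10 higher) and 2.78 against BMS641+BMS961 (9 of 10), as for Fos (ENSMUSG00000021250) at 224, 55.7 and 13.4 CPM under ATRA, BMS753 and BMS641+BMS961. They were 1.12 and 1.03 at day 4. Surface epithelium genes under ATRA had medians of 2.69 (3 of 4 higher, 1 lower), 2.22 (3 of 5 higher) and 2.00 (5 of 7) against BMS753 at the 3 days, and 2.54 (3 of 4, 1 lower), 1.78 (2 of 5) and 1.74 (4 of 7) against BMS641+BMS961, as for the keratin Krt19 (ENSMUSG00000020911) at 206 CPM under ATRA and 15.5 CPM under BMS641+BMS961 at day 4. Surface epithelium-like cells were 0 of 17331 under ATRA at day 4, 1 at day 8 and 0.162% at day 16 (0.412% under BMS753), so at day 4 these genes came from other clusters. Mesoderm genes under ATRA lay at −0.82, 1.28 and 2.12 against BMS753 and −1.64, −0.94 and 0.01 against BMS641+BMS961 at days 4, 8 and 16. Nascent mesoderm-like cells at day 16 were 6.29%, 0.304% and 21.3% under ATRA, BMS753 and BMS641+BMS961, but 0.200%, 0.320% and 22.4% within the Ftl1 kind, and 1.26% under ATRA at resolution 2. Ventral neural tube genes had medians of 2.51 and 2.29 at day 4, with the floor plate factor Foxa2 (ENSMUSG00000037025) at 22.0, 0.283 and 0.699 CPM. Oligodendrocyte lineage genes lay at 1.40 and 1.11 at day 4 and at 0.47 and 0.83 at day 16, endothelial genes at 1.05 and 0.92 at day 4, and neural crest genes at −0.63 and 0.75 at day 16. Cholesterol synthesis genes under BMS753 lay at 0.76 against BMS641+BMS961 at day 8 and −0.57 at day 16, and hypoxia and glycolysis genes at 0.67 and −0.26, with the lactate dehydrogenase gene Ldha (ENSMUSG00000063229) at 556 against 1098 CPM at day 16. Ependymal and choroid plexus genes lay at −0.62 and −0.39 there. Proneural genes under ATRA lay at 1.07 against BMS753 at day 8 and −0.68 at day 16. Receptor genes stayed between −0.06 and 0.54 in the 9 comparisons. Hox groups 10 to 13 were measured at day 8 under BMS641+BMS961, at −1.96 for BMS753 and −0.45 for ATRA against it. The macrophage and the forebrain and midbrain lists never had 3 measured members.

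Clusters 2, 21, 23, 25 and 29 stayed unnamed for the threshold alone. The best match was pluripotent for clusters 21, 23 and 25, smooth muscle for 2 and surface epithelium for 29. Cluster 2 held 38.1% of cells under ATRA at day 4, and 1.72%, 1.11% and 0.358% under ATRA, BMS753 and BMS641+BMS961 at day 8. Cluster 21 held 25.3% under BMS641+BMS961 and 1.502% under BMS753 at day 4, and at most 0.0305% elsewhere. Cluster 23 held 7.63% under ATRA at day 4, and 0.438%, 0.750% and 0.381% under ATRA, BMS753 and BMS641+BMS961 at day 8. Cluster 25 held 0.946%, 0.856% and 1.62% in that order at day 4, 0.602%, 1.51% and 3.83% at day 8, and at most 0.0270% at day 16. Cluster 29 held 1.78% under ATRA and 0.392% under BMS753 at day 16. Cluster 6 (31.1% under ATRA at day 4) passed the threshold for primitive or parietal endoderm, and stayed unnamed for its low depth.

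A set of 18 genes among 8853 was over 2-fold lower in the libraries labelled BMS753 day 8 and BMS641+BMS961 day 16 than in each of the other 7, and 0 were higher. Scand1 stood at 13.4 and 10.7 CPM in these against 100.3 to 241 in the others, Map1lc3a (ENSMUSG00000027602) at 18.7 and 28.1 against 83.7 to 158, and Nenf (ENSMUSG00000037499) at 22.1 and 25.8 against 70.9 to 232. These libraries share neither a treatment nor a day. Among the other 35 pairs of libraries the most such genes were 81, for BMS753 and BMS641+BMS961 at day 4, which share a day. Other pairs that share neither treatment nor day had at most 2.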
